A study of Mus musculus with 14 samples.

How the data were processed

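Per the labels' protocols, BALB/c marrow progenitors were cultured for 8 days with recombinant granulocyte-macrophage colony-stimulating factor and fed on days 3 and 6. Cells were treated for 1 h with 5 µM CA074Me, 5 µM CLIK148 or the same volume of DMSO (0.01%), then given CpG at 25 µg/mL, TNF at 500 U/mL or nothing. The time from stimulus to harvest is not given in the sources used here. Per the same protocols, RNA was isolated on Qiagen RNeasy columns and 100 ng was amplified and labelled with the IVT Express kit for Affymetrix mouse genome arrays. The design text names 7 conditions and 2 independent experiments, so replicate numbers 1 and 2 were read as experiments 1 and 2, each array a separate culture. Over the 21 pairs of groups, the difference between replicates correlated with r from 0.455 to 0.935, so the replicate numbers do pair the arrays. With 2 arrays per group, precision is limited by their number.

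Per the submitters' processing notes, the deposited log2 values are RMA expression summaries made by the authors in R 3.0.1, a method that corrects background, normalises quantiles and summarises the probes of a probe set. The RMA settings are not given in the sources used here. The table holds 45101 probe sets for each of 14 arrays. Array medians lay between 7.48 and 7.54 log2, minima between 6.07 and 6.22, maxima between 15.2 and 15.6, and 48.7% to 50.6% of an array's values exceeded the overall median of 7.52. The difference between 3' and 5' control probe sets ranged from -0.060 to 0.030 log2 for Gapdh and from 0.184 to 0.318 for Actb. The first 2 principal components of the tested genes held 54.4% and 26.8% of the variance. No array was left out.

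The array's annotation gave 34945 probe sets 1 gene, 932 several genes and 9160 none, beside 64 control probe sets. Of the single-gene probe sets 34741 matched a mouse RefSeq gene by identifier, and 0 symbols needed updating. For each of 18193 genes the probe set with the highest mean was kept, and 12192 genes above the overall median on at least 2 arrays were tested. Among the probe sets without a single gene, which were analysed only as a count, 30 of 3044 bright enough changed with CpG.

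Group differences were fitted with limma 3.58.1 in R 4.3.3, all 14 arrays and 7 groups in 1 model with 7 residual degrees of freedom, moderated standard errors and 2-sided tests. P values were adjusted by the Benjamini-Hochberg method over the 12192 genes within each of 12 comparisons, and genes under 0.05 are said to have changed. Confidence intervals are 95%. This fit was planned without the experiment and ignores the pairing of arrays. Standard errors and intervals printed without mention of the block therefore include the gap between experiments. In the inhibitor comparisons and interactions, fewer than 0.05 of the tested genes had an unadjusted p under 0.05, with or without the block. Unchanged groups would give about that share, so these tests are too cautious there. A count of 0 in them does not show absence of an effect. An alternative fit added the experiment as a block (6 residual degrees of freedom), and its value is printed beside the counts of changed genes in a comparison that it moved over 1.5-fold and beside the genes and lists named in the text whose call it altered. The limit set by the number of arrays was gauged on simulated values with each gene's mean and moderated spread and known changes added. Noise was drawn independently for each array. Without the block, the gap between experiments, which paired arrays share, thus entered as independent noise. The shares recovered hold for such noise and need not hold for these arrays. Of added changes of 1 log2 in the CLIK148 comparison 71.2% were recovered (90.9% with the block), and of 0.5 log2 22.1% (66.2% with the block). Fits that leave out 1 array are without the block and mix a comparison with the gap between experiments.

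The 23 gene lists were written from textbook knowledge and the series labels before the data were examined. They cover interferon, NF-kB, Th1 and Th2 mediators, cytokines, chemokines, maturation, antigen presentation, cathepsins, lysosome, cholesterol, oxidative stress, unfolded protein, cell cycle, glycolysis, pattern recognition, matrix proteases and 5 sets of cell type markers. Each was tested with camera in limma at a preset correlation between genes of 0.01, with p adjusted over the 23 lists of a comparison. The same test with a correlation estimated from the data is given beside each list called, and with it no list had an adjusted p under 0.05 in any comparison. A list's median is the median log2 change of its tested members, and called members are counted over all genes and again with the adjustment over the list alone.

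Genes named in the text were picked by a rule fixed in advance. It takes the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, the 3 largest called members of each called list or otherwise its 2 largest as values, and 21 study genes of cathepsins, Th1 and Th2 mediators and costimulation. Where under 5 genes passed, the 5 with the smallest unadjusted p in each direction were added as values. The text names a part of what the rule gives. Cxcl5 and the genes reported only from the fit to unstimulated arrays were chosen after their values were seen. For the correlation of CpG and TNF changes, 50 simulated data sets with no effect and the same shared solvent arrays gave the correlation that sharing alone yields.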

Results

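Dendritic cells were grown for 8 days from the bone marrow of BALB/c mice with granulocyte-macrophage colony-stimulating factor and profiled on 14 arrays, 2 for each of 7 groups. For 1 h the cells received the solvent DMSO, the cathepsin B inhibitor CA074Me or the cathepsin L inhibitor CLIK148. They then received CpG oligonucleotide, a ligand of Toll-like receptor 9 labelled as a pro-Th1 stimulus, tumour necrosis factor alpha (TNF), labelled as pro-Th2, or no stimulus. CLIK148 was combined with CpG and CA074Me with TNF, so each inhibitor was measured alone and under 1 stimulus. Cathepsins B and L are lysosomal proteases, and the Th1 and Th2 labels refer to the T helper responses that dendritic cells can prime. Each group's arrays come from 2 independent experiments, and their expression profiles correlated with r from 0.961 for solvent plus CpG to 0.985 for CLIK148 alone. Of 18193 genes with a probe set of their own, 12192 were bright enough to test. The 95% confidence interval of a group difference had a median width of 0.301 log2 to either side, and 0.203 with the experiment as a block.

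CpG raised genes of dendritic cell activation. The chemokine gene Ccl1 rose by 4.54 ± 0.62 log2 (standard error; limma adjusted p = 0.0139; n = 2 arrays per group), or 23.2-fold, from a mean of 8.55 to 13.09. The integrin subunit gene Itgb8 rose by 3.87 ± 0.66 log2 (adjusted p = 0.0289), and Il12b, which encodes the p40 subunit shared by IL-12 and IL-23, rose by 3.71 ± 0.67 (adjusted p = 0.0341), or 13.1-fold. Gpr31b rose by 3.38 ± 0.46, the scavenger receptor gene Marco by 2.99 ± 0.54, and Nfkbiz, an inducible nuclear IkB protein, by 2.52 ± 0.27 log2. The costimulatory receptor gene Cd40 rose by 2.33 ± 0.42 log2 (adjusted p = 0.0326), the Toll-like receptor gene Tlr1 by 1.62 ± 0.16, and the chemokine genes Ccl22 and Ccl17 by 1.08 ± 0.19 and 0.59 ± 0.11 log2. Lad1 (ladinin) rose by 2.34 ± 0.13 log2, with the smallest adjusted p of the comparison (0.000228), and by 2.32 and 2.36 log2 in experiments 1 and 2.

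Other genes were lower with CpG. The C-type lectin genes Clec10a and Mgl2 fell by 1.60 ± 0.28 and 1.36 ± 0.17 log2 (limma adjusted p = 0.0326 and 0.0091). Cass4 fell by 1.32 ± 0.18 log2, the neonatal Fc receptor gene Fcgrt by 1.26 ± 0.25, the sphingosine-1-phosphate phosphatase gene Sgpp1 by 1.21 ± 0.21, and the prostaglandin E2 receptor gene Ptger3 by 1.20 ± 0.18. The integrin gene Itgb7, whose product pairs with alpha 4 or alpha E chains on leukocytes, fell by 1.19 ± 0.11 log2 (adjusted p = 0.00347). In limma, 234 genes changed with CpG at adjusted p under 0.05, 130 higher and 104 lower, and 69 of them at least 2-fold (51 and 18; 249 with the block, 145 and 104).

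The size of the CpG response depended on the experiment. Ifit1, an interferon-induced gene, was 3.18 log2 higher in experiment 1 and 1.13 log2 higher in experiment 2 (mean 2.15 ± 0.99, limma adjusted p = 0.291). Il12b was 4.79 and 2.64 log2 higher, Il6 3.99 and 1.64, and Cxcl10 3.49 and 1.02. The standard deviation of the change over all genes was 0.546 log2 in experiment 1 and 0.267 in experiment 2, with r = 0.667 between them. With the experiment as a block in the model, 2420 genes changed (753 higher, 1667 lower), among them Ifit1 (adjusted p = 0.0281), Il6 (2.82 ± 0.74 log2 unblocked, 0.0951 unblocked and 0.0266 blocked), Tnf (1.81 ± 0.98 log2, 0.364 and 0.0326) and Cxcl9 (2.43 ± 0.97 log2, 0.233 and 0.0402). Without the solvent array of experiment 1 only Lad1 passed, without that of experiment 2 the count was 10, and without the CpG array of experiment 1 or 2 the counts were 22 and 1611. With only the compared groups in the limma fit 0 genes passed (1036 at unadjusted p under 0.05), and with array weights 48 did, Il12b, Itgb8, Gpr31b, Marco, Cd40, Ccl22, Ccl17, Clec10a, Fcgrt, Sgpp1 and Ptger3 not among them. Fcgrt also lost its call without the filter on dim genes (adjusted p = 0.0544), with reference-gene scaling (0.0602) and with cyclic loess (0.0646).

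**Figure D1:**
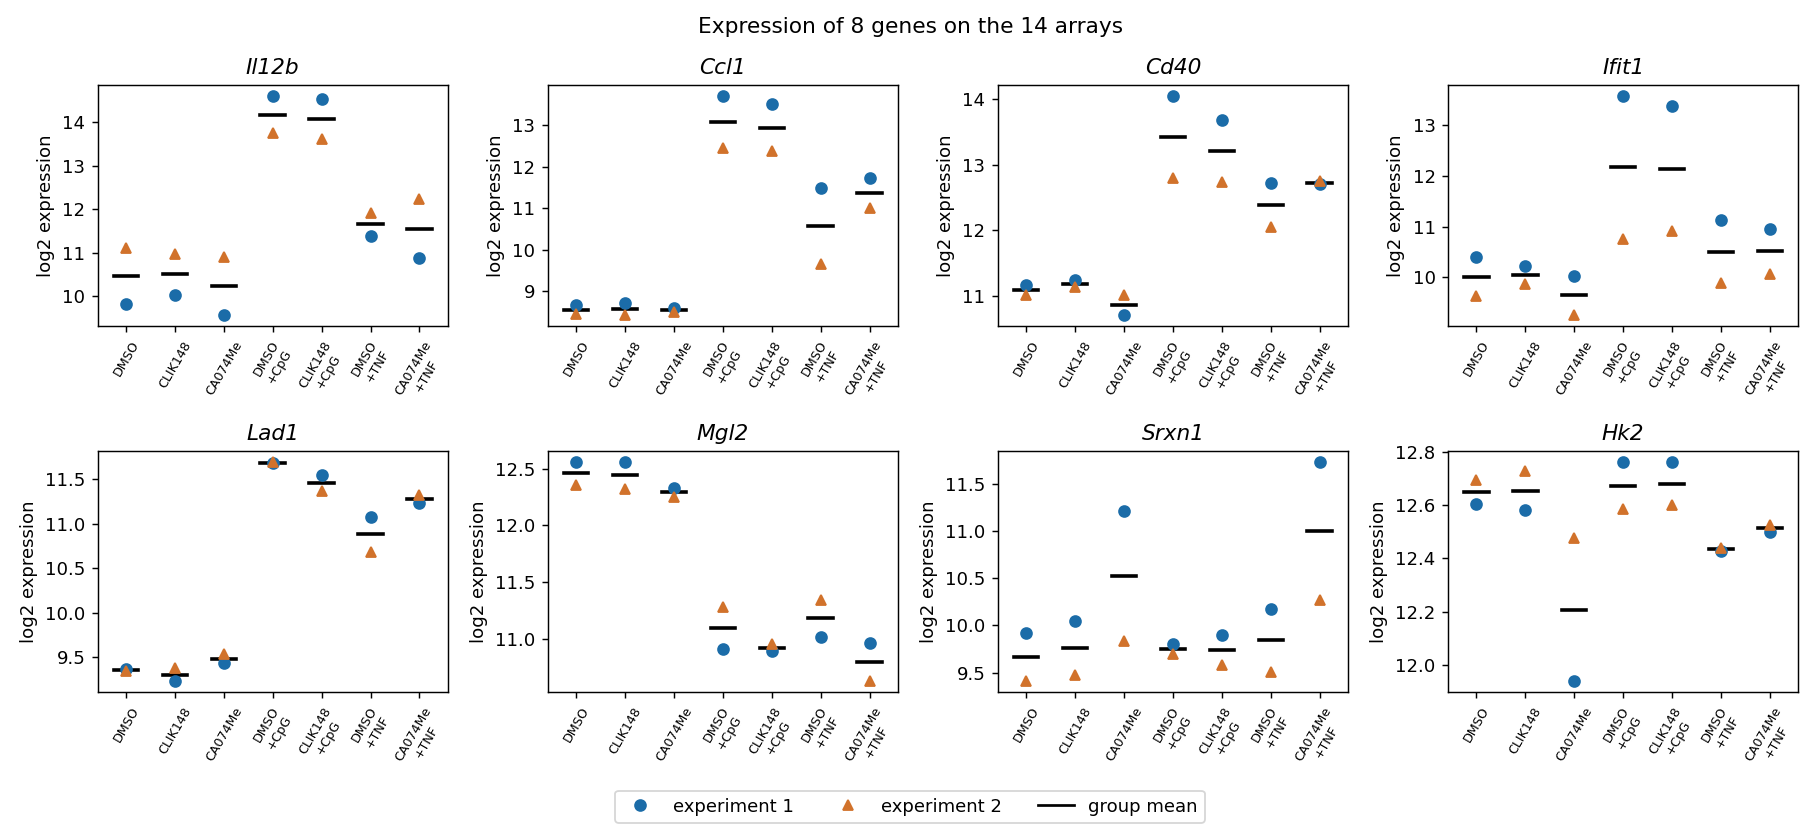
Log2 expression of 8 genes on the 14 arrays (circles experiment 1, triangles experiment 2, black bars group means). Il12b rose by 4.79 log2 with CpG in experiment 1 and by 2.64 in experiment 2, whereas Lad1 rose by 2.32 and 2.36.

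Gene lists fixed from the labels showed activation as a programme. All 25 members of the dendritic cell maturation list lay above 0 with CpG (median 0.77 log2, 5 higher over all genes and 16 adjusted over the list alone; camera adjusted p = 3.36e-16). Of 24 NF-kB targets and feedback regulators, which NF-kB switches on after Toll-like receptor signalling, 9 were higher (15 over the list alone), among them Nfkbiz, Gadd45b (1.42 ± 0.23 log2) and Traf1 (1.32 ± 0.17), with a median of 0.78 (adjusted p = 8.1e-20). Of 24 chemokines 5 were higher (6 over the list alone; median 0.81, adjusted p = 7.48e-09). With an estimated correlation between genes, adjusted p = 0.0762 for each of these lists.

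Interferon and Th1 genes stood highest with CpG in experiment 1. The type I interferon list had a median of 1.37 log2 (2.22 and 0.50 in experiments 1 and 2) with all 28 members above 0, of which 0 passed limma over all genes or the list alone and 7 passed with the block (camera adjusted p = 1.29e-11, and adjusted p = 0.396 with an estimated correlation). Of 18 Th1-associated mediators, Il12b and the transcription factor gene Irf8 (1.16 ± 0.23 log2; its call lost with reference-gene scaling, adjusted p = 0.0605) were higher, 5 over the list alone, at a median of 1.17 (camera adjusted p = 1.86e-09; adjusted p = 0.183 with an estimated correlation). The Irf8 call was also lost with the mean of a gene's probe sets, without the filter on dim genes and over all probe sets. The inflammatory cytokines had a median of 0.55 (1 of 18 higher, 3 over the list alone; adjusted p = 2.69e-06, 0.183 with an estimated correlation). MHC class I presentation, with Tap1 at 0.72 ± 0.16 (limma adjusted p = 0.0621, 0.0174 with the block), had a median of 0.39 (0 of 16 over all genes, 1 over the list alone; adjusted p = 1e-06, 0.182 with an estimated correlation). Il12a, the p35 subunit gene, was 0.36 ± 0.45 log2 higher and Cd86 0.63 ± 0.73, neither with an adjusted p under 0.05. Il10, Il4, Il13 and Nos2 were dim, at most 7.68, 7.85, 7.80 and 7.86 log2 on any array against an overall median of 7.52.

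As lists, markers of conventional dendritic cells and of division lay below solvent with CpG, with 3 and 0 members called. Neither list passed with an estimated correlation. Clec10a, Mgl2 and Cd24a (-0.64 ± 0.11 log2; adjusted p = 0.102 with the mean of its probe sets) were the 3 called members of 12 conventional dendritic cell markers (4 over the list alone; median -0.71 log2, camera adjusted p = 0.00949, and adjusted p = 0.182 with an estimated correlation). All 28 cell cycle genes lay below 0 (median -0.32; 0 called, 12 with the block; adjusted p = 0.000682, 0.623 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at -1.02 ± 0.31 log2 and thymidine kinase Tk1 at -0.78 ± 0.24 (limma adjusted p = 0.135 for both, 0.000876 and 0.00223 with the block). Without the CpG array of experiment 1 the cell cycle list lost its call (-0.10, adjusted p = 0.0933), and without that of experiment 2 the marker list did, at a median still of -0.59 (adjusted p = 0.073). Ctsb, Ctsl and Ctss, which encode cathepsins B, L and S, were 0.05 ± 0.18, 0.01 ± 0.24 and 0.01 ± 0.16 log2 from solvent, and the 19 cathepsins and their inhibitors had a median of -0.00 (camera adjusted p = 0.945). The lysosome list had -0.17 (0.454), MHC class II -0.23 (0.393), collagenases -0.04 (0.945), macrophage markers -0.25 (0.945), granulocyte markers 0.11 (0.224), lymphocyte and plasmacytoid markers 0.02 (0.443), and erythroid and stromal markers 0.03 (0.524).

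Smaller list shifts with CpG lost their calls without single arrays, at medians given beside each p, and some also with all arrays kept. The cholesterol synthesis list had a median of 0.23 log2 (camera adjusted p = 0.000221), with the isoprenoid isomerase gene Idi1 higher by 1.05 ± 0.13 log2 (limma adjusted p = 0.00896), and without the CpG array of experiment 2 its median was 0.09 (adjusted p = 0.0934). Pattern recognition had a median of 0.27 with Tlr1 called (adjusted p = 0.00281) and glycolysis and hypoxia 0.08 (adjusted p = 0.00548). Without the CpG array of experiment 1 these were -0.01 (adjusted p = 0.555) and 0.07 (adjusted p = 0.0638), and pattern recognition had 0.09 (0.0519) without the solvent array of experiment 2. An estimated correlation gave adjusted p = 0.396 for cholesterol synthesis and for glycolysis and 0.407 for pattern recognition. Th2-associated mediators had a median of 0.04 (adjusted p = 0.0205) with Ccl17 and Ccl22 higher and Mgl2 lower, the unfolded protein list 0.10 (adjusted p = 0.0245), and the oxidative stress list 0.11 (adjusted p = 0.0419). With an estimated correlation adjusted p = 0.183, 0.623 and 0.536, and the block left Th2-associated mediators at adjusted p = 0.0857. Without the CpG array of experiment 1 the Th2-associated list had a larger median of 0.10 (adjusted p = 0.315) and the oxidative stress list 0.03 (0.183). Without the CpG array of experiment 2 the unfolded protein list had -0.09 (adjusted p = 0.135), and without the solvent array of experiment 1 -0.14 (0.435). In those fits the oxidative stress median was larger, at 0.17 (0.0591) and 0.21 (0.0541). Without the solvent array of experiment 2 the Th2-associated list had 0.03 (adjusted p = 0.0667) and the oxidative stress list 0.07 (0.0723). With all arrays kept, the oxidative stress list lost its call without the filter on dim genes (adjusted p = 0.108), with reference-gene scaling (0.066), cyclic loess (0.139), the mean of a gene's probe sets (0.0529) and array weights (0.0506). The unfolded protein list lost it without the filter (adjusted p = 0.0755), and Th2-associated mediators and glycolysis with cyclic loess (0.0612 each).

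TNF changed fewer genes, and several of those that CpG changed. Lad1 rose by 1.53 ± 0.13 log2 (limma adjusted p = 0.0089; 1.71 and 1.34 in experiments 1 and 2; n = 2 arrays per group), and Relb, a subunit of noncanonical NF-kB, by 0.86 ± 0.12 log2 in the mean and in each experiment (adjusted p = 0.0493). The Relb call was lost over all probe sets (0.061), with reference-gene scaling (0.0915), with cyclic loess (0.069) and with the trended prior (0.0641). The magnesium transporter gene Nipal1 rose by 1.22 ± 0.16 log2, Cyria by 1.03 ± 0.12, the ephrin gene Efna2 by 0.97 ± 0.10 and the small GTPase gene Rhoc by 0.96 ± 0.11. Mgl2 fell by 1.28 ± 0.17 log2 (adjusted p = 0.0348), Itgb7 by 0.91 ± 0.11 (adjusted p = 0.0233), and Arhgap15 and Pgm2l1 by 0.78 ± 0.10 and 0.74 ± 0.10. Itgb7 lost its call with reference-gene scaling (adjusted p = 0.0651) and cyclic loess (0.0949), and Cyria with reference-gene scaling (0.0545). Cyria, Arhgap15 and Pgm2l1 lost theirs with the mean of a gene's probe sets (0.0689, 0.0773 and 0.0914). In limma 14 genes changed, 10 higher and 4 lower, 4 of them at least 2-fold, and 379 did with the block (139 higher, 240 lower), 39 of them at least 2-fold. Among these were Ccl1 (2.03 ± 0.62 log2, adjusted p = 0.42 unblocked and 0.0289 blocked), Ccl22 (0.85 ± 0.19, 0.235 and 0.0419) and Idi1 (0.67 ± 0.13, 0.111 and 0.0125). Il12b was 1.18 ± 0.67 log2 higher (adjusted p = 0.779). Leaving out the solvent array of experiment 1 or 2 left 0 genes (limma, 512 and 647 at unadjusted p under 0.05), leaving out the TNF array of experiment 1 left Lad1, and leaving out that of experiment 2 left 5 genes. Only the compared groups in the fit gave 0 (926 at unadjusted p under 0.05), array weights 34 and cyclic loess 23.

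TNF shifted the maturation and NF-kB lists as groups. The 25 maturation genes had a median of 0.53 log2 (0.82 and 0.34 in experiments 1 and 2; 1 higher over all genes, 11 over the list alone; camera adjusted p = 3.09e-17), with Cd40 at 1.29 ± 0.42. The NF-kB list had a median of 0.46 with Relb called (8 over the list alone; adjusted p = 1.19e-16), and with an estimated correlation adjusted p = 0.161 for both lists. Chemokines (median 0.35, 1 over the list alone; adjusted p = 6.57e-05) and Th1-associated mediators (0.41; adjusted p = 0.00077) had 0 members called over all genes, with adjusted p = 0.293 and 0.566 with an estimated correlation. All 28 cell cycle genes lay below 0, with Tk1 at -0.65 ± 0.24 (limma adjusted p = 0.0131 with the block; median -0.42, 0 called and 4 with the block; adjusted p = 1.13e-05, 0.566 with an estimated correlation). Without the TNF array of experiment 1 the cell cycle list lost its call (-0.11, adjusted p = 0.112), as did the inflammatory cytokines (0.33, adjusted p = 0.00577; 0.12 and 0.101 without that array; 0.566 with an estimated correlation). Cholesterol synthesis had a median of 0.11 (adjusted p = 0.00577) and the oxidative stress list 0.14 (0.0119), which were 0.02 (0.353) and 0.06 (0.053) without the solvent array of experiment 2. An estimated correlation gave adjusted p = 0.566 for both. The Th2-associated list had a median of 0.07 (adjusted p = 0.0396, 0.37 with an estimated correlation), the interferon list 0.16 (adjusted p = 0.0396, 0.743) and MHC class I 0.10 (adjusted p = 0.0441, 0.566). Without the TNF array of experiment 1 the oxidative stress list had 0.05 (adjusted p = 0.185), the Th2-associated list 0.03 (0.194), the interferon list -0.09 (0.706) and MHC class I 0.03 (0.18). Without the solvent array of experiment 2 the last 3 had 0.06 (adjusted p = 0.151), 0.03 (0.283) and 0.07 (0.151), and without the TNF array of experiment 2 MHC class I had 0.09 (0.0522). With all arrays kept, cyclic loess left the interferon, MHC class I, Th2-associated, inflammatory and oxidative stress lists uncalled (adjusted p = 0.185, 0.0868, 0.0889, 0.0627 and 0.0505), and reference-gene scaling the first 4 (0.299, 0.0951, 0.0787 and 0.0529). Without the filter on dim genes the interferon, MHC class I, Th2-associated and oxidative stress lists lost their calls (adjusted p = 0.245, 0.205, 0.334 and 0.0683). The block called 2 more lists, conventional dendritic cell markers (-0.45; adjusted p = 0.0626 unblocked and 0.0366 blocked) and granulocyte markers (0.08; 0.119 and 0.0388), with adjusted p = 0.599 and 0.714 with the block and an estimated correlation.

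CpG and TNF shared 13 genes, 9 higher and 4 lower with both, Lad1, Mgl2 and Itgb7 among them. Independent lists would share 0.107 higher and 0.0341 lower genes, but both comparisons subtract the same solvent arrays, which part of the excess may come from. Across all genes the changes correlated at r = 0.762, and simulations with shared solvent arrays and no effect gave 0.503. Their highest overlap, 0 genes (limma), is fixed by having no effects to call and does not gauge how many of the 13 come from the shared arrays. The covariance of the changes exceeded the simulated one by 0.0553. With the block 332 genes were shared (113 higher, 219 lower), against 8.58 and 32.8 for independent lists. With 2 solvent arrays, that group was not split between the comparisons. Leaving out 1 array left 0 to 16 shared genes, 0 of them without either solvent array.

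Compared directly, CpG and TNF differed in Siah2. This E3 ubiquitin ligase gene was 1.07 ± 0.08 log2 higher with CpG (limma adjusted p = 0.00333; 1.02 and 1.12 in experiments 1 and 2) and was the 1 gene changed. With the block 53 genes differed (42 higher, 11 lower), including Nfkbiz (2.19 ± 0.27 log2, adjusted p = 0.0631 unblocked and 0.018 blocked), Ccdc149 (1.03 ± 0.11, 0.0524 and 0.0167), Ccl1 (2.51 ± 0.62, 0.472 and 0.0386) and Cass4 (-1.15 ± 0.18, 0.116 and 0.018). Il12b was 2.53 ± 0.67 log2 higher with CpG than with TNF (adjusted p = 0.522). With only the compared groups in the fit 0 genes passed (limma, 255 at unadjusted p under 0.05). Siah2 passed when the CpG array of experiment 1 was left out, and 0 genes did without the CpG array of experiment 2 or the TNF array of experiment 1 or 2 (2266, 375 and 617 at unadjusted p under 0.05). The mean of a gene's probe sets and a trended prior each gave 2.

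Most activation lists stood higher with CpG than with TNF, mainly in experiment 1. The interferon list had a median difference of 1.09 log2 (1.84 and 0.41 in experiments 1 and 2; camera adjusted p = 6.62e-13), with Ifit2 at 1.81 ± 1.01 and Isg20 at 3.28 and 0.53. Th1-associated mediators had 0.72 (adjusted p = 1.46e-07), NF-kB targets 0.28 (2.25e-09), inflammatory cytokines 0.46 (0.000133), chemokines 0.37 (8.37e-06), maturation genes 0.23 (0.000322) and MHC class I 0.26 (1.6e-06), each with 0 members called. With an estimated correlation adjusted p = 0.39, 0.37, 0.356, 0.37, 0.356, 0.392 and 0.356 in that order. Glycolysis had 0.17 (adjusted p = 0.000133, 0.37 with an estimated correlation), pattern recognition 0.20 (0.00553, 0.532), cholesterol synthesis 0.18 (0.00969, 0.591) and the unfolded protein list 0.13 (0.00553, 0.591). Without the CpG array of experiment 1 the medians of the interferon, Th1, NF-kB, inflammatory, chemokine, maturation and MHC class I lists were 0.14, 0.21, 0.16, 0.05, 0.29, 0.05 and 0.11 (adjusted p = 0.844, 0.66, 0.144, 0.844, 0.479, 0.892 and 0.421), those of glycolysis and pattern recognition 0.13 and -0.02 (0.129 and 0.593). Without the CpG array of experiment 2 cholesterol synthesis had -0.02 (adjusted p = 0.524) and the unfolded protein list 0.04 (0.11), and without the TNF array of experiment 1 the latter had -0.02 (0.257). Without the TNF array of experiment 2 the maturation list had 0.12 (adjusted p = 0.0623) and pattern recognition 0.05 (0.784).

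**Figure D2:**
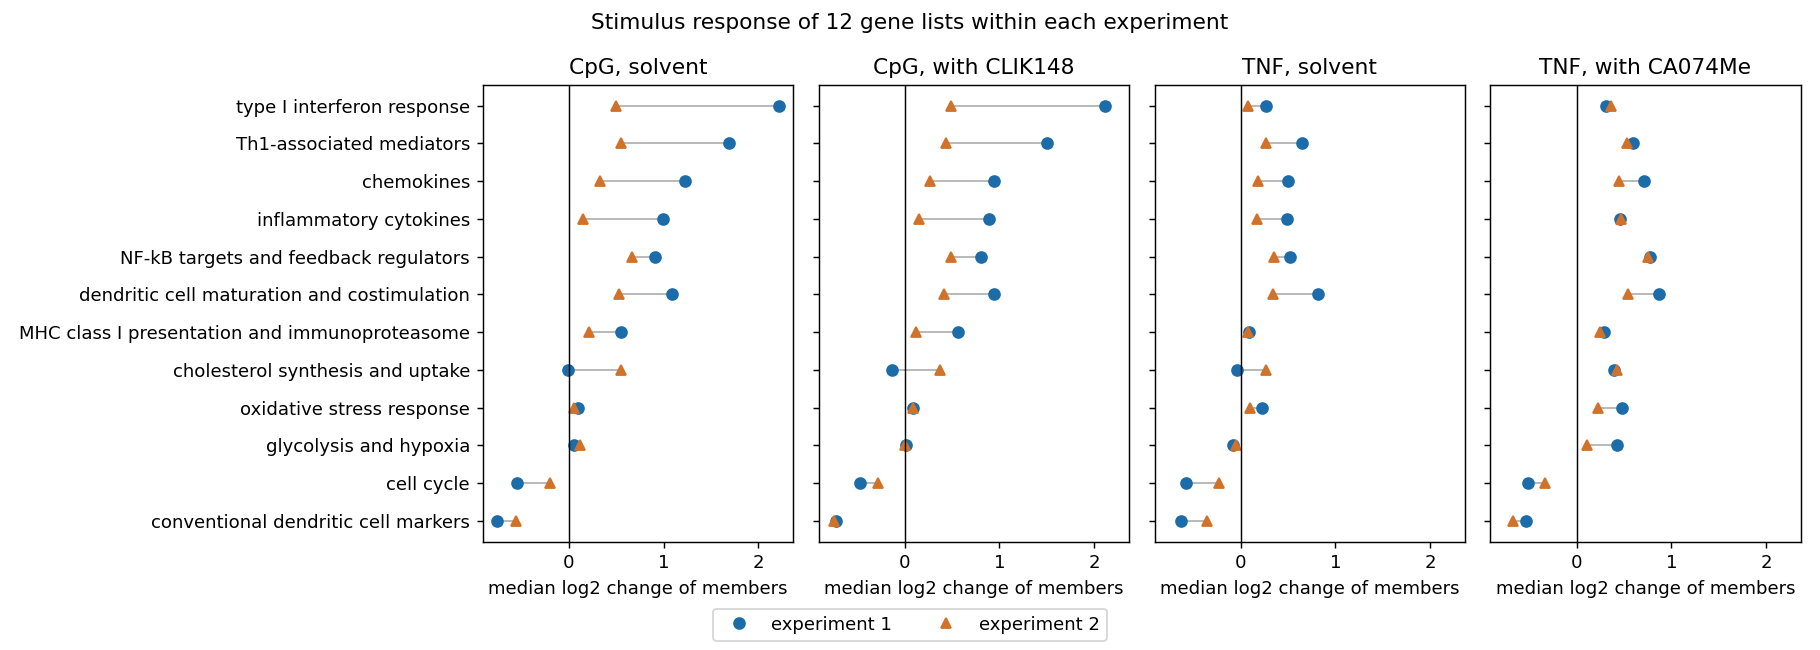
Median log2 change of the members of 12 gene lists within experiment 1 (circles) and experiment 2 (triangles) for CpG and TNF, each with solvent and with the inhibitor. The interferon list's median was 2.22 and 0.50 log2 with CpG and 2.12 and 0.49 with CpG after CLIK148, with 0 members called in either and adjusted p = 0.396 and 0.354 with an estimated correlation (camera).

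CLIK148 alone left the measured genes close to solvent. Ctsl, which encodes its target cathepsin L, was -0.00 ± 0.24 log2 from solvent, Ctsb -0.10 ± 0.18 and Ctss -0.06 ± 0.16, and Il12b and Cd40 0.04 ± 0.67 and 0.10 ± 0.42. The genes with the smallest unadjusted p included Zfp202 and Spring1 (0.19 ± 0.08 log2 each), Zzef1 (-0.22 ± 0.07) and Map3k9 (-0.19 ± 0.07). In limma 0 genes changed, with or without the block (12 at unadjusted p under 0.05, 45 with the block), and the changes in experiments 1 and 2 correlated at r = 0.045. Both 12 and 45 are far fewer than 0.05 of the 12192 tested genes, the share that unchanged groups would give. The fits thus overstate the spread for this comparison, and 0 calls does not show absence of an effect. Cholesterol synthesis was the 1 list shifted: 17 of 18 members lay above 0 (median 0.11 log2; 0.05 and 0.14 in experiments 1 and 2; camera adjusted p = 2.05e-06), including the sterol enzymes Cyp51 (0.17 ± 0.19) and Sc5d (0.17 ± 0.15). An estimated correlation gave adjusted p = 0.991, and without the solvent array of experiment 2 or the CLIK148 array of experiment 1 the medians were 0.03 (adjusted p = 0.665) and 0.07 (0.192). Granulocyte markers had a median of 0.06 (adjusted p = 0.083, and 0.00841 with the block, 0.914 with the block and an estimated correlation).

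With CA074Me alone no single gene passed, and genes of oxidative defence lay above solvent while genes of glycolysis and hypoxia lay below it. Sulfiredoxin Srxn1 was 0.86 ± 0.54 log2 higher than with solvent (1.29 and 0.43 in experiments 1 and 2; n = 2 arrays per group), Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, 0.85 ± 0.40 (1.22 and 0.48), and glutathione reductase Gsr 0.44 ± 0.12. Of 16 oxidative stress genes 13 lay above 0 (median 0.38 log2; 0.54 and 0.24 in experiments 1 and 2; camera adjusted p = 5.02e-14, and adjusted p = 0.0632 with an estimated correlation). Of 21 glycolysis and hypoxia genes, which hypoxia-inducible factors drive, 2 lay above 0 (median -0.20; -0.33 and -0.13; adjusted p = 3.52e-16, 0.0632 with an estimated correlation). With the block and an estimated correlation no list had an adjusted p under 0.313. The oxygen-sensing prolyl hydroxylase Egln3 was at -0.56 ± 0.25 log2, adenylate kinase Ak4 at -0.53 ± 0.16, hexokinase Hk2 at -0.44 ± 0.15 and the collagen prolyl hydroxylase subunit P4ha1 at -0.39 ± 0.12. Outside these lists the selective autophagy receptor Sqstm1 was 0.28 ± 0.08 log2 higher, Acta1 0.27 ± 0.07 higher, Noct -0.26 ± 0.07 and Appl1 -0.22 ± 0.07. Ctsb, which encodes its target cathepsin B, was 0.01 ± 0.18 log2 from solvent, Ctsl 0.03 ± 0.24, and Arg1 -0.70 ± 0.70 (-0.96 and -0.44).

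In limma 0 single genes changed with CA074Me alone (67 at unadjusted p under 0.05, 0 and 336 with the block), and 0 members of any list passed over all genes or the list alone. Both 67 and 336 are fewer than 0.05 of the tested genes, so these tests are too cautious here. An alternative added after the data were seen, the block in a fit to the unstimulated arrays only, called 36 genes, among them Srxn1 (adjusted p = 0.0455), Gclm (0.0399), Lipa (0.0327) and Arg1 (0.0231). NF-kB targets had a median of -0.13 log2 (camera adjusted p = 0.000552), with Tnfaip3 at -0.33 ± 0.23 and Bcl3 at -0.29 ± 0.16. Cholesterol synthesis also had -0.13 (adjusted p = 0.00296), with Fdft1 at -0.26 ± 0.30 and Hmgcs1 at -0.26 ± 0.20. The lysosome list had 0.02 (adjusted p = 0.0223), with the acid lipase gene Lipa at 0.52 ± 0.54. An estimated correlation gave adjusted p = 0.998 for all 3. Without the solvent array of experiment 1 the NF-kB and cholesterol lists had -0.07 (adjusted p = 0.262) and -0.06 (0.977). Without the CA074Me array of experiment 1 the NF-kB, cholesterol and lysosome lists had -0.10 (0.0997), -0.04 (0.212) and -0.09 (0.0997). Without the solvent array of experiment 2 the lysosome list had -0.04 (0.688). Its call was also lost with all arrays kept, without the filter on dim genes (adjusted p = 0.286), with the mean of a gene's probe sets (0.0856) and with reference-gene scaling (0.064).

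**Figure D3:**
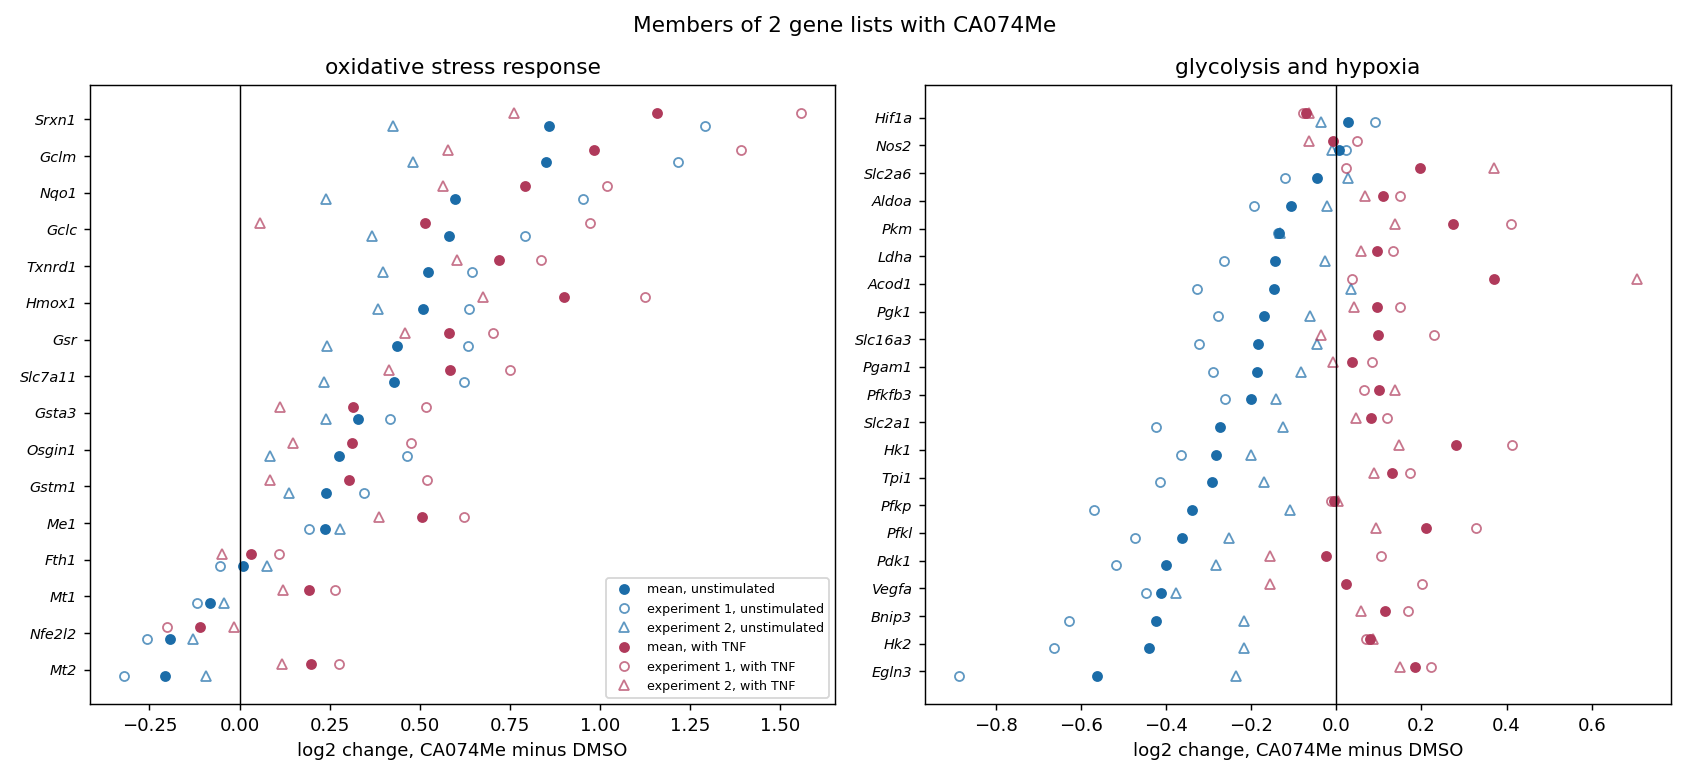
Log2 change with CA074Me of each member of the oxidative stress list (16) and the glycolysis and hypoxia list (21), unstimulated (blue) and with TNF (red); filled points are means, open circles and triangles experiments 1 and 2. The glycolysis list's median was -0.20 log2 unstimulated and 0.10 with TNF, with 0 members called in either and adjusted p = 0.0632 and 0.487 with an estimated correlation (camera).

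CLIK148 set against CA074Me gave differences in lists that CA074Me also shifted, from the same CA074Me arrays, so that the overlap of lists is in part arithmetic. With CLIK148 relative to CA074Me, Gclm stood at -0.86 ± 0.40 log2 (95% interval -1.76 to 0.03), Srxn1 at -0.76 ± 0.54 and Gsr at -0.35 ± 0.12, against 0.54 ± 0.25 for Egln3 and 0.39 ± 0.12 for the platelet phosphofructokinase Pfkp. The sterol enzymes Fdft1 and Hsd17b7 were 0.39 ± 0.30 and 0.36 ± 0.13 log2 higher. In limma 0 genes differed (58 at unadjusted p under 0.05, 0 and 288 with the block). The block in a fit to the unstimulated arrays only, added after the data were seen, called 42 (33 higher, 9 lower), Gclm among them (adjusted p = 0.0326) and Srxn1 not (0.0753). The glycolysis list had a median of 0.23 log2 (camera adjusted p = 1.14e-17), the oxidative stress list -0.33 and cholesterol synthesis 0.25 (5.23e-12 each), with 0 members called, and with an estimated correlation adjusted p = 0.0655, 0.0976 and 0.252. NF-kB targets had 0.13 (adjusted p = 0.000653) and the lysosome list -0.04 (0.00248), with adjusted p = 0.716 for both with an estimated correlation. Without the CLIK148 array of experiment 1 the NF-kB list had a median of 0.18 (adjusted p = 0.0842), and without the CA074Me array of experiment 1 the lists had 0.12 (0.0688) and 0.04 (0.184). Without the CLIK148 array of experiment 2 the lysosome list had -0.02 (0.698). Both comparisons with solvent called 0 genes, so their overlap of 0 was fixed in advance and does not gauge a shared effect. Across genes the effects correlated at r = 0.285, against 0.505 simulated from the shared solvent arrays alone.

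CpG after CLIK148 changed many of the genes that it changed in solvent. Ccl1 rose by 4.37 ± 0.62 log2 (limma adjusted p = 0.0176), Itgb8 by 3.82 ± 0.66, Gpr31b by 3.28 ± 0.46, Nfkbiz by 2.40 ± 0.27, Lad1 by 2.16 ± 0.13 and Tlr1 by 1.50 ± 0.16. The cell cycle inhibitor gene Cdkn2b rose by 1.69 ± 0.25 log2, Rel by 1.24 ± 0.21, Traf1 by 1.21 ± 0.17 and Relb by 0.79 ± 0.12. Clec10a, Mgl2, Cass4, Nceh1 and Itgb7 fell by 1.56 ± 0.28, 1.52 ± 0.17, 1.29 ± 0.18, 1.19 ± 0.16 and 1.06 ± 0.11 log2. The calls of Clec10a and Relb were lost with reference-gene scaling (adjusted p = 0.0543 and 0.0523), that of Itgb8 without the filter on dim genes (0.0511), and that of Clec10a also with 5 other settings that keep all 14 arrays. Il12b was 3.57 ± 0.67 log2 higher (adjusted p = 0.057, 0.00809 with the block) and Cd40 2.02 ± 0.42 (0.0659, 0.00815 with the block). In limma 99 genes changed, 50 higher and 49 lower (2075 with the block, 491 and 1584), and 94 of them also changed in solvent-treated cells, on arrays with no sample in common. Those arrays come from the same 2 experiments, and both tests use the same estimate of each gene's spread. The overlap is therefore not an independent replication. Changes with and without CLIK148 correlated at r = 0.970, and over the 2420 genes called with the block in solvent the median ratio was 0.909, with 73.8% of them smaller after CLIK148. Choosing genes by their call in solvent itself favours a ratio below 1. Without the CLIK148 array of experiment 1 or 2 the count was 1, and without the CLIK148 plus CpG array of experiment 1 or 2 it was 5 or 44. It was 155 with array weights, 175 with cyclic loess, and 0 with only the compared groups (limma, 1483 at unadjusted p under 0.05).

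Within CpG-treated cells CLIK148 gave no single-gene call. Il12b was -0.10 ± 0.67 log2 from solvent (95% interval -1.63 to 1.42), Il6 -0.22 ± 0.74 (-1.89 to 1.45), Tnf -0.27 ± 0.98 and Cd40 -0.21 ± 0.42 (-1.15 to 0.73). These intervals include the gap between experiments. Within experiments 1 and 2 the differences were -0.07 and -0.13 log2 for Il12b, -0.31 and -0.13 for Il6, -0.32 and -0.21 for Tnf and -0.36 and -0.05 for Cd40. With the block over all arrays the Il12b interval was -1.43 to 1.23. In a fit added after the data were seen, the block with only these 4 arrays, the intervals were -0.27 to 0.07 for Il12b, -0.40 to -0.04 for Il6, -0.44 to -0.09 for Tnf and -0.40 to -0.02 for Cd40. That fit has 1 residual degree of freedom, and with it 0 genes changed (limma, 440 at unadjusted p under 0.05; adjusted p = 1 for these 4). The genes with the smallest unadjusted p included Cop1 and Taf1b (-0.22 ± 0.06 and -0.22 ± 0.07 log2), Trim62 (0.22 ± 0.07) and Krt33b (0.24 ± 0.08). In limma 0 genes changed (68 at unadjusted p under 0.05, 0 and 226 with the block). Both 68 and 226 are fewer than 0.05 of the tested genes, so these tests are too cautious here. All 24 NF-kB targets lay below 0 (median -0.11 log2; -0.11 and -0.12 in experiments 1 and 2; camera adjusted p = 0.0225, and adjusted p = 0.982 with an estimated correlation), with Gadd45b at -0.22 ± 0.23 and Junb at -0.21 ± 0.10. This direction turned without the solvent plus CpG array of experiment 1 (0.08) or the CLIK148 plus CpG array of experiment 2 (0.05). Those fits mix the comparison with the gap between experiments. Within experiments 1 and 2 the median was -0.11 and -0.12, so the turns do not show an unstable direction. With cyclic loess camera gave adjusted p = 0.137.

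The interaction, whether CLIK148 altered the CpG response, also gave 0 genes in limma (15 at unadjusted p under 0.05, 0 and 61 with the block). Il12b had a difference of -0.14 ± 0.95 log2 (95% interval -2.30 to 2.01) and Tnf -0.30 ± 1.38. Krt33b (0.33 ± 0.11), Wnk2 (0.29 ± 0.10), Smc6 (-0.36 ± 0.13) and the AP-1 subunit gene Jund (-0.38 ± 0.13) had among the smallest unadjusted p. NF-kB targets had a median of -0.11 (camera adjusted p = 0.0467) and cholesterol synthesis -0.13 (0.0106), with adjusted p = 0.997 for both with an estimated correlation. Fits that leave out 1 array mix the interaction with the gap between experiments, so they cannot tell an unstable effect from that gap. Without the solvent plus CpG array of experiment 1 or the CLIK148 plus CpG array of experiment 2 the NF-kB median was 0.12 or 0.08. It was -0.02 without the solvent array of experiment 2 (adjusted p = 0.488) and unmoved at -0.11 without the CLIK148 array of experiment 1, where the call was lost (0.278). The cholesterol median was 0.07 (adjusted p = 0.688) without the CLIK148 plus CpG array of experiment 1 and 0.06 (0.72) without the solvent plus CpG array of experiment 2. It was -0.07 (adjusted p = 0.732) without the solvent array of experiment 2 and -0.10 (0.41) without the CLIK148 array of experiment 1. With all arrays kept, the NF-kB call was lost without the filter on dim genes (adjusted p = 0.129), with the mean of a gene's probe sets (0.0715), cyclic loess (0.127), the trended prior (0.0606) and array weights (0.0501). The cholesterol call was lost without the filter (adjusted p = 0.0607) and with the mean of probe sets (0.0715).

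After CpG with CLIK148 the activation lists were higher as in solvent-treated cells. Maturation genes had a median of 0.72 log2 (2 higher, 11 over the list alone; camera adjusted p = 4.72e-16), NF-kB targets 0.67 (5 higher, 14 over the list alone; 7.27e-19) and chemokines 0.69 (1 higher; 1.4e-08), with adjusted p = 0.0826 for each with an estimated correlation. Interferon genes, with Ifit1 at 2.09 ± 0.99 (limma adjusted p = 0.327, 0.0335 with the block), had a median of 1.35 (0 higher; 3.78e-13, 0.354 with an estimated correlation), Th1-associated mediators 1.06 (0 higher, 4 over the list alone; 2e-09, 0.183) and inflammatory cytokines 0.46 (2.03e-06, 0.183). Conventional dendritic cell markers had -0.74 (3 lower; adjusted p = 0.00547, 0.154 with an estimated correlation). Cell cycle genes had -0.38 (adjusted p = 0.000341, 0.568 with an estimated correlation, and -0.11 with 0.065 without the CLIK148 plus CpG array of experiment 1).

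Under TNF, oxidative defence genes again lay higher with CA074Me. Srxn1 was 1.16 ± 0.54 log2 higher than with TNF alone (1.56 and 0.76 in experiments 1 and 2; n = 2 arrays per group), Gclm 0.98 ± 0.40 (1.39 and 0.58), Gsr 0.58 ± 0.12 and Sqstm1 0.56 ± 0.08 (0.62 and 0.51). Of the 16 oxidative stress genes 15 lay above 0 (median 0.51 log2; 0 called over all genes, 2 over the list alone; camera adjusted p = 2.15e-16, and adjusted p = 0.0792 with an estimated correlation). All 18 cholesterol synthesis genes lay above 0 (median 0.16; 0.17 and 0.16 in experiments 1 and 2; adjusted p = 2.82e-06, 0.487 with an estimated correlation), with lanosterol synthase Lss at 0.34 ± 0.24 and Hsd17b7 at 0.25 ± 0.13. The signalling adaptor Sla was at -0.45 ± 0.13 log2, Rgs2 at -0.41 ± 0.13, the leukotriene receptor gene Cysltr1 at -0.57 ± 0.19, and the lymphocyte receptor gene Ly9 at 0.55 ± 0.12. Ctsb was 0.14 ± 0.18 log2 from TNF alone. In limma 0 genes changed (98 at unadjusted p under 0.05), and with the block 1 did, the neutrophil-attracting chemokine gene Cxcl5 (1.05 ± 0.95 log2, adjusted p = 1 unblocked and 0.0142 blocked; 1.13 and 0.97 in experiments 1 and 2), named here after its values were seen. The block with only these 4 arrays, added after the data were seen, also called Cxcl5 alone (adjusted p = 0.0399).

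NF-kB targets had a median of 0.13 log2 under TNF with CA074Me (camera adjusted p = 0.000131), with Relb at 0.28 ± 0.12, the lysosome list 0.09 (0.00026; 0 called, 1 over the list alone), with Lipa at 0.69 ± 0.54, and glycolysis 0.10 (0.000666). Chemokines had 0.14 (adjusted p = 0.0147), with Ppbp at 1.09 ± 0.59 and Ccl1 at 0.80 ± 0.62, maturation genes 0.13 (0.00703), with Cd40 at 0.34 ± 0.42, and MHC class I 0.11 (0.00972). With an estimated correlation adjusted p = 0.487 for the first 4, 0.608 for maturation and 0.542 for MHC class I. Without the TNF array of experiment 2 all 6 lost their calls, at adjusted p = 0.658, 0.284, 0.126, 0.827, 0.605 and 0.284 in that order. Their medians were then 0.05, 0.04, 0.08, 0.11, 0.15 and 0.06, so that glycolysis, chemokine and maturation genes kept about the same size. Without the CA074Me plus TNF array of experiment 1 the calls of the lysosome, glycolysis, chemokine and MHC class I lists were lost (0.987, 0.509, 0.218 and 0.306), at medians of -0.01, 0.08, 0.33 and 0.07, the chemokine median being larger. Without that of experiment 2 the chemokine and maturation lists had 0.18 (0.0651) and 0.07 (0.226). Cyclic loess left MHC class I at adjusted p = 0.066.

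TNF called more genes in cells given CA074Me, but the interaction, which tests that difference, called 0 genes with or without the block. Lad1 rose by 1.79 ± 0.13 log2 (limma adjusted p = 0.00226), Nipal1 by 1.65 ± 0.16, Tmem39a by 1.65 ± 0.18, the phosphatidylserine receptor gene Havcr1 by 1.86 ± 0.26 and Fnbp1l by 1.33 ± 0.16. NF-kB genes followed, with Traf1 up by 1.29 ± 0.17 log2, Relb by 1.24 ± 0.12 (1.20 and 1.28 in experiments 1 and 2) and Nfkb2 by 0.87 ± 0.12. Ccl22, Cxcl16 and Ccl17, ligands that attract T cells, rose by 1.07 ± 0.19, 0.70 ± 0.13 and 0.59 ± 0.11 log2, and the sterol genes Idi1 and Hsd17b7 by 0.95 ± 0.13 and 0.72 ± 0.13. With reference-gene scaling the calls of Ccl22, Cxcl16 and Ccl17 were lost (adjusted p = 0.0531, 0.0604 and 0.0717), and with the mean of a gene's probe sets those of Cxcl16 and Hsd17b7 (0.059 and 0.108). Mgl2, P2ry6, Tent5a, Rab19 and Itgb7 fell by 1.49 ± 0.17, 1.34 ± 0.26, 1.32 ± 0.18, 1.26 ± 0.14 and 1.26 ± 0.11 log2. P2ry6 lost its call with cyclic loess (adjusted p = 0.051) and 3 other settings that keep all arrays. Cd40 was 1.87 ± 0.42 log2 higher (adjusted p = 0.0793, 0.0102 with the block). In limma 159 genes changed, 108 higher and 51 lower (1354 with the block, 605 and 749), including all 14 called in solvent, on arrays with no sample in common. These too come from the same 2 experiments and share each gene's estimated spread, so the overlap is not an independent replication. Changes with and without CA074Me correlated at r = 0.901, and over the 379 genes called with the block in solvent the median ratio was 1.19, with 20.8% of them smaller after CA074Me. Without the CA074Me array of experiment 1 or 2 the counts were 5 and 53, and without the CA074Me plus TNF array of experiment 1 or 2 they were 59 and 7. The count was 239 over all probe sets, 369 with array weights, and 0 with only the compared groups (limma, 1757 at unadjusted p under 0.05). Reference-gene scaling gave 138, with 57.2% of them higher against 67.9%.

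NF-kB targets stood higher as a group with TNF after CA074Me in both experiments. All 24 lay above 0 (median 0.77 log2; 0.77 and 0.76 in experiments 1 and 2; 5 higher, 16 over the list alone; camera adjusted p = 2.54e-19), and maturation genes had a median of 0.66 (3 higher, 15 over the list alone; 9.29e-16), with adjusted p = 0.122 for both with an estimated correlation. Cholesterol synthesis had 0.44 (2 higher, 4 over the list alone; adjusted p = 3.83e-08), chemokines 0.53 (3 higher, 5 over the list alone; 0.000138) and Th2-associated mediators 0.12 (2 higher, 1 lower; 0.025), with adjusted p = 0.225 for each with an estimated correlation. Without the CA074Me plus TNF array of experiment 1 the Th2-associated list had 0.01 (adjusted p = 0.186). All 21 glycolysis and hypoxia genes lay above 0 (median 0.24; 0 higher, 3 over the list alone; adjusted p = 7.45e-08, 0.187 with an estimated correlation), with the phosphofructokinase-2 gene Pfkfb3 at 0.98 ± 0.28 log2 (limma adjusted p = 0.17, 0.00102 with the block). Cell cycle genes had -0.43 with all 28 below 0 (adjusted p = 6.1e-06, 0.56 with an estimated correlation). The oxidative stress list had 0.36 (adjusted p = 0.00295, 0.372 with an estimated correlation), and without the CA074Me array of experiment 2 or the CA074Me plus TNF array of experiment 1 it had 0.12 (adjusted p = 0.161) and 0.05 (0.865).

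The interaction of CA074Me with TNF placed glycolysis first among the lists. Hexokinase Hk1 had a difference of 0.56 ± 0.16 log2, the osmotic stress factor Nfat5 0.51 ± 0.17 and Noct 0.54 ± 0.09, against -0.31 ± 0.10 for Kif15 and -0.33 ± 0.10 for Acta1. In limma 0 genes passed (80 at unadjusted p under 0.05, 0 and 303 with the block), Cd40 (0.57 ± 0.59) and Arg1 (0.63 ± 1.00) included. Of the 21 glycolysis and hypoxia genes 19 lay above 0 (median 0.36 log2; 0.55 and 0.22 in experiments 1 and 2; camera adjusted p = 6.86e-16, and adjusted p = 0.0872 with an estimated correlation). All 24 NF-kB targets lay above 0 (median 0.26; 0.28 and 0.27; adjusted p = 6.15e-08), as did all 18 cholesterol synthesis genes (0.29; 0.44 and 0.15; adjusted p = 1.78e-08), with adjusted p = 0.497 for both with an estimated correlation. Maturation genes had 0.18 (adjusted p = 0.0138) and MHC class I 0.16 (0.0341, 0.0685 with the block), with adjusted p = 0.94 for both with an estimated correlation. The maturation list lost its call without the solvent or TNF array of experiment 2 (0.13 and 0.21, adjusted p = 0.467 and 0.493) or the CA074Me plus TNF array of experiment 2 (0.17, 0.118), and its median fell to 0.01 (0.896) without the CA074Me array of experiment 1. The MHC class I list lost its call without the solvent array of experiment 1 (0.12, adjusted p = 0.172) or 2 (0.19, 0.0568). It also lost it without the TNF or CA074Me array of experiment 2 (0.09 each, 0.274 and 0.212) or the CA074Me plus TNF array of experiment 1 (0.09, 0.328), and with all arrays kept it did so with cyclic loess (0.229) and the mean of a gene's probe sets (0.397).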

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

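The tests of the CpG pattern, of macrophage content and of the share of glycolysis members were chosen after the result was seen. Those on single arrays behind the oxidative stress and glycolysis shifts, and on a broader CA074Me effect, were written before their values were computed.

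The interferon list's response to CpG was 2.22 log2 in experiment 1 and 0.50 in experiment 2. A weak CpG array in experiment 2 would leave the CLIK148 plus CpG pair, on other arrays, without the gap, but there the ratio of experiment 2 to experiment 1 was 0.231. A higher starting level in experiment 2 would show in unstimulated arrays, where the list was lower in experiment 2 instead, by -0.178 to -0.309 log2. Compressed values on all stimulated arrays of experiment 2 would shrink the NF-kB response to TNF with CA074Me, whose ratio was 0.980. With solvent, however, that list's medians of 0.52 and 0.36 log2 were also smaller in experiment 2. Over all genes the standard deviation of the TNF change was smaller there too, at 0.192 against 0.304 log2 with solvent and 0.283 against 0.326 after CA074Me. A smaller response in experiment 2 was thus not particular to CpG, and 1 list in 1 pair cannot exclude compression. A difference between the cultures, the CpG or its timing was not tested and stays open, though one in CpG alone would leave the TNF responses unexplained.

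The oxidative stress list's median was above 0 with CA074Me in all 4 pairs of arrays, by at least 0.240 log2, which speaks against 1 unusual array, although the pairs come from only 2 experiments. More macrophages would raise the macrophage list as well, yet its median change was -0.112 times that of the oxidative stress list unstimulated and -0.128 times with TNF. Of the 50 other genes most higher with CA074Me unstimulated, the median change with TNF was 0.0201 log2, above 94.9% of matched random sets and just below their 95th percentile of 0.0203. That meets the outcome written for no shared effect, but by less than the sampling error of the random sets, so for these 50 genes alone an effect and its absence cannot be told apart. The 50 most lower genes had a median of 0.0671 log2, above the 95th percentile of 0.0327. For these genes that is opposite to such an effect and argues against it. Glycolysis and hypoxia genes were not left out of the 50, however, so this may in part restate that list's shift. Over all genes, list members included, the CA074Me changes unstimulated and with TNF correlated at r = 0.161 (0.202 and 0.136 in experiments 1 and 2). Those comparisons use separate arrays from the same experiments. The correlation goes the other way, so a broader shared effect stays open.

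The glycolysis and hypoxia list differed between the unstimulated and TNF settings of CA074Me by 0.36 log2 in the median. If 1 unusual array were the cause, the sign would depend on the experiment, but the smaller of the medians in experiments 1 and 2 was 0.221 log2. A few members were not the cause either, since 90.5% of the 21 members had an interaction above 0. Both settings use different arrays for each group, and a change of culture conditions such as medium use or density with CA074Me was not tested.

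The other list shifts that differed between settings were, for CLIK148 and CpG, NF-kB targets (-0.11 log2) and cholesterol synthesis (-0.13), and for CA074Me and TNF, NF-kB targets (0.26), maturation genes (0.18), MHC class I (0.16) and cholesterol synthesis (0.29). The NF-kB shift with CLIK148 turned to 0.12 without the solvent plus CpG array of experiment 1 and to 0.08 without the CLIK148 plus CpG array of experiment 2, and the cholesterol shift to 0.07 without the CLIK148 plus CpG array of experiment 1. Fits that leave out 1 array mix the interaction with the gap between experiments and cannot tell an unstable effect from that gap. For CA074Me and TNF the maturation median fell to 0.01 without the CA074Me array of experiment 1, and the MHC class I median was 0.09 without the CA074Me array of experiment 2, and the call was lost in each. Of the probe sets with no single gene, 30 changed with CpG (18 higher, 12 lower), 271 with the block, and they were not followed further.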

How the results depend on the processing

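The averaged effects, the changes within each experiment the fits to unstimulated arrays alone and the block with only the compared groups were added after the data were seen; the other settings were fixed in advance. Of 2880 values for genes named in the text, 2395 kept call and direction, 380 lost a call, 48 gained a call and 57 turned; for all genes the naming rule gives, 6337 of 7337 kept both and 429 turned. Of 1242 list values 996 kept call and direction, 235 lost a call, and in 11 the direction given by camera turned. That direction need not be the sign of the median. The median changed sign in 21 values, 9 of these 11 and 12 of those that lost a call. The inhibitor values near 0 turn most, and leaving out 1 array of a pair leaves its comparison mixed with the difference between experiments. A group then has a lone array, assumed to vary like the other groups. For the remaining changes the cause was not tested.

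With the experiment as a block, 2420 genes changed with CpG, 379 with TNF, 53 between CpG and TNF, 2075 with CpG after CLIK148, 1354 with TNF after CA074Me and 1 with CA074Me under TNF, and CpG and TNF shared 332. No other comparison's count moved with the block. With only the compared groups in the limma fit, the counts were 0 for CpG, 0 for TNF, 0 for CpG against TNF, 0 for CpG after CLIK148 and 0 for TNF after CA074Me (1036, 926, 255, 1483 and 1757 at unadjusted p under 0.05). Array weights gave 48 for CpG, 34 for TNF, 155 for CpG after CLIK148 and 369 for TNF after CA074Me. All probe sets gave 358 for CpG and 239 for TNF after CA074Me. The trended and robust prior gave 2 for CpG against TNF, as did the mean of a gene's probe sets, with which Ctsb was at -0.049 log2 with CpG and -0.014 with CA074Me.

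Cyclic loess gave 23 genes for TNF, 175 for CpG after CLIK148 and an overlap of 20, and placed Ctsl at -0.018 log2 and Ctss at -0.061 with CpG, Ctsl at 0.0175 with CLIK148 and 0.0135 with CLIK148 under CpG, and Ctss at 0.018 with CA074Me. Reference-gene scaling placed Ctsl at 0.0325 log2 with CLIK148 and 0.0061 with CLIK148 under CpG, and Ctss at 0.0325 with CA074Me. Its largest shift of an array was -0.124 log2, and with it the calls of Dusp2, Fcgrt, Zfp36l2 and Irf8 with CpG were lost, as were those of Cyria, Mreg, Relb and Itgb7 with TNF, Clec10a and Relb with CpG after CLIK148, and Ccl22, Ccl17 and Cxcl16 with TNF after CA074Me. Cyclic loess lost Dusp2 and Fcgrt with CpG, Relb and Itgb7 with TNF, Clec10a with CpG after CLIK148 and P2ry6 with TNF after CA074Me. The mean of a gene's probe sets lost Zfp36l2, Irf8, Cxcl16 and Cd24a with CpG, Cyria, Tmem176a, Arhgap15 and Pgm2l1 with TNF, and Cxcl16 and Hsd17b7 with TNF after CA074Me. Without the filter on dim genes the calls of Dusp2, Fcgrt, Zfp36l2, Man2a2 and Irf8 with CpG, Itgb8 and Clec10a with CpG after CLIK148, and P2ry6 and Ccl17 with TNF after CA074Me were lost. All probe sets lost Dusp2, Man2a2 and Irf8 with CpG, Relb with TNF, Clec10a with CpG after CLIK148, and P2ry6 and Ccl17 with TNF after CA074Me, and the trended prior lost Man2a2, Relb, Clec10a and P2ry6 in the same comparisons.

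The averaged effects gave 0 genes for CA074Me (limma, 76 at unadjusted p under 0.05), 1666 for CpG and 470 for TNF, and with the block 1 (Cxcl5), 5136 and 2588. The block with only the compared groups gave 1 gene for CA074Me under TNF (Cxcl5). The unstimulated arrays alone with the block gave 36 for CA074Me and 42 for CLIK148 against CA074Me.

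Leaving out 1 array at a time, the counts ranged from 1 to 1611 for CpG, 0 to 5 for TNF, 0 to 1 for CpG against TNF, 1 to 44 for CpG after CLIK148, 5 to 59 for TNF after CA074Me, and 0 to 16 for the overlap. Where a count was 0, limma gave 375 to 2266 genes at unadjusted p under 0.05. With CpG the log2 changes ranged from -0.075 to 0.185 for Ctsb, -0.201 to 0.223 for Ctsl, -0.154 to 0.182 for Ctss, -0.026 to 0.749 for Il12a and -0.020 to 1.28 for Cd86, and with TNF from -0.212 to 1.30 for Tnf. Between CpG and TNF the inflammatory list ranged from 0.0505 to 0.793 and pattern recognition from -0.0214 to 0.389.

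With CLIK148 alone these ranges were -0.0209 to 0.367 for Sc5d, -0.234 to 0.0253 for Ctsb, -0.260 to 0.255 for Ctsl, -0.172 to 0.0520 for Ctss and -0.607 to 0.686 for Il12b. With CA074Me alone they were -0.0258 to 1.07 for Lipa, -0.184 to 0.201 for Ctsb, -0.179 to 0.245 for Ctsl, -0.124 to 0.106 for Ctss, -0.0932 to 0.152 for the lysosome list and -0.209 to -0.0387 for the cholesterol list. Between CLIK148 and CA074Me they were -0.0566 to 1.09 for Vegfa and -0.175 to 0.0434 for the lysosome list.

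Under CpG, CLIK148 gave -0.474 to 0.0271 for Gadd45b, -0.175 to 0.117 for Ctsl, -0.564 to 0.359 for Il12b, -0.905 to 0.466 for Il6, -1.53 to 1.00 for Tnf, -0.836 to 0.420 for Cd40 and -0.328 to 0.0760 for the NF-kB list. Under TNF, CA074Me gave -0.127 to 1.72 for Ccl1 and -0.0419 to 0.323 for Ctsb. In the interaction of CLIK148 and CpG the ranges were -0.789 to 0.505 for Il12b, -1.57 to 0.968 for Tnf, -0.287 to 0.122 for the NF-kB list and -0.323 to 0.0652 for the cholesterol list, and in that of CA074Me and TNF -0.101 to 1.37 for Arg1.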

Other observations

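The averaged effects, the fit to unstimulated arrays alone and the fit to the 4 arrays with CpG below were chosen after the result was seen, and of the tests cited those on macrophages and on the CpG gap were too. In a limma fit to the 6 unstimulated arrays with the experiment as a block, 36 genes changed with CA074Me, 12 higher and 24 lower, where the planned fits gave 0. The antioxidant genes Srxn1 (0.86 ± 0.15 log2, adjusted p = 0.0455) and Gclm (0.85 ± 0.14, 0.0399) were among those higher, with haem oxygenase Hmox1 (0.51 ± 0.07, 0.0231) and thioredoxin reductase Txnrd1 (0.52 ± 0.08, 0.0254), all targets of the transcription factor Nrf2. Among those lower were the selenium-binding protein gene Selenbp1 (-0.76 ± 0.07, 0.0031), arginase Arg1 (-0.70 ± 0.10, 0.0231), the cholesterol exporter Abca1 (-0.48, 0.0231) and the mTOR regulator Ddit4 (-0.48, 0.0254). CLIK148 gave 0 genes in this fit, and 42 separated CLIK148 from CA074Me (33 higher, 9 lower).

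This fit was 1 of 16 settings for that comparison and the only one with a call, and it has 2 residual degrees of freedom. The median residual standard deviation was 0.0567 log2 over the unstimulated arrays and 0.0910 over all 14. Leaving out the stimulated arrays without the block gave 0 genes (limma, 116 at unadjusted p under 0.05), and the block with all arrays gave 0 (336), so the calls need both choices together. In 50 simulations without an effect 0 gave a call. Their noise was drawn independently for each gene and array, so they cannot gauge noise that genes on an array share. Nor do they allow for the choice of this fit among 16 settings, so they do not support the 36 calls. Averaged over unstimulated and TNF-treated cells, CA074Me gave 0 genes (limma) and 1 with the block, Cxcl5 (0.72 log2, adjusted p = 0.0178).

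CA074Me may activate Nrf2, many of whose targets are in the oxidative stress list. The list's median was at least 0.240 log2 in each of 4 pairs of arrays, and macrophage markers did not rise with it (-0.112 of its median). The pairs come from only 2 experiments and so are not 4 independent replicates. No member passed limma over all genes in the planned fits, and with an estimated correlation camera gave adjusted p = 0.0632 unstimulated and 0.0792 with TNF, so the list shift itself is not firm. Whether this follows from loss of cathepsin B activity or from the chemistry of the compound is open, since CLIK148 is the only other inhibitor here and has a different target. Cells lacking cathepsin B, given CA074Me and assayed for Srxn1 and Gclm, would separate these.

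Lower glycolysis genes with CA074Me alone and higher ones with TNF could reflect a lower hypoxia-inducible factor activity in resting cells that TNF overrides. This cause was not tested. In the interaction 90.5% of the list members lay above 0 and the smaller experiment had 0.221 log2, which restates the shift and is no evidence for the cause. The list was not among those called for TNF in solvent-treated cells. The shifts are not firm: 0 members passed limma over all genes, and with an estimated correlation camera gave adjusted p = 0.0632 unstimulated, 0.487 with TNF and 0.0872 for the interaction. With TNF the list also lost its call without the TNF array of experiment 2 (0.126) or the CA074Me plus TNF array of experiment 1 (0.509). Measuring oxygen use and the stabilised factor under both conditions would test it.

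After CLIK148 the interferon list's CpG response in experiment 2 was 0.231 of that in experiment 1, and the standard deviation of the response over all genes was 0.261 against 0.495 log2. The gap in both pairs could come from a property of the whole experiment, which was not tested. Under CpG, Il12b, Il6, Tnf and Cd40 were below solvent with CLIK148 in each experiment, by 0.05 to 0.36 log2. The block with only the 4 arrays concerned put Il12b between -0.27 and 0.07 log2 and Tnf between -0.44 and -0.09 (95% intervals, adjusted p = 1 for each). The block over all arrays gave wider intervals, -1.43 to 1.23 and -1.36 to 0.83. The narrow intervals rest on 1 residual degree of freedom and a spread borrowed from other genes, so a small reduction of these mediators by cathepsin L inhibition is not shown. More independent experiments with solvent and CLIK148 side by side would narrow this.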
